A study of Mus musculus with 38 samples.

How the data were processed

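The series holds 38 samples of mouse E14 embryonic stem cells. The 14 RNA sequencing libraries, in 5 groups, were analysed. Values of the 24 whole-genome bisulfite samples (12 groups) were not used here. Per the labels' protocols, poly(A) RNA was made into strand-specific libraries with the NEBNext Ultra II Directional kit and read as 50-base single ends on an Illumina HiSeq2500. Cells grew without feeders on gelatin and were passaged every 2 days. The submitters' processing notes name Trim Galore 0.6.5, Bismark 0.22.3 (a tool for bisulfite reads), HISAT2 and the genome build GRCm38. The name of the deposited file also points to SeqMonk. The version, the counting options, the gene annotation and whether reads were counted by strand are not given in the sources used here.

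The deposited table gives 1 value per gene and library for 25965 Ensembl genes with coordinates, on a log2 scale of reads per 1000000 reads (log2 RPM). Its values showed that the authors had treated the libraries in 2 ways. In 8 libraries (MEKi/L, 2i/L and GSK3i/L at 24 days) the values were plain log2 RPM. On a linear scale at least 99.96% of them were whole multiples of the value of 1 read (within 0.02 of a read), and a gene with 0 reads stood at 0.9 of a read. The other 6 (S/L and GSK3i/L at 8 days) had been matched to 1 shared distribution, with sorted values that differed by at most 0.083 above 2 RPM. 2i/L against MEKi/L lies within the plain columns. GSK3i/L against S/L lies within the matched ones and the other 5 comparisons cross the 2 treatments, which both limit the balance of higher and lower genes. Matching can hide a shift of all genes. All value columns of the table could be assigned to a library from their names. Symbols were taken as deposited (25899 distinct), and 25035 of the identifiers were also named in a reference table of gene names.

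Scaling totals of the 8 plain libraries ran from 10550000 to 15760000 reads. Depths of the 6 matched libraries were approximated from the level of genes near 100 reads, at 8080000 to 18410000 reads. A floor of 3 reads per library corresponded to 0.33 RPM in S/L, 0.23 RPM in MEKi/L, 0.25 RPM in GSK3i/L at 8 and at 24 days and 0.22 RPM in 2i/L. It was used for genes with 0 reads in a group, and the resulting folds are lower bounds, rounded down. For genes with 1 to 3 reads in a group, levels are given without a fold. Floors cover counting error only. The 10 most abundant genes held between 3.92% and 6.62% of the RPM of all genes.

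The table of log2 values was tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend and robust variances). All 14 libraries entered 1 fit with group as the only term, so that all groups shared 1 estimate of the spread. The test had been chosen for either counts or normalized values, and the form for normalized values was used because the values were on a log scale. Genes with at least 0.5 RPM in at least 3 libraries were kept, 14980 in all. Counts of rising and falling genes are those with a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. For members of gene lists no minimum fold applied. Levels are means ± SD on the linear RPM scale with 0 reads taken as 0. Log2 fold changes are differences of mean log2 values ± SE, with 0 reads at the 0.9-read value, which understates changes of genes near 0. Labels call the libraries replicates 1 to 3 (2 and 3 at 24 days).

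A total of 23 gene lists were tested with camera from limma (two-sided, correlation between genes preset at 0.01) in each of the 7 comparisons, with Benjamini-Hochberg adjustment over the 161 pairs. The lists were DNA methylation writers and maintenance, DNA demethylation, naive pluripotency, general pluripotency, formative and primed pluripotency, MEK-ERK targets and feedback, Wnt/beta-catenin targets, LIF-STAT3 targets, BMP-SMAD and ID genes, primitive endoderm, primitive streak and mesoderm, neural, trophoblast, and fibroblast and mesenchymal markers, germline genes with methylated promoters, the two-cell-like state, imprinted genes, cholesterol biosynthesis, p53 targets, ATF4 and amino acid stress, glycolysis and hypoxia, Polycomb repressive complexes, and mitochondrially encoded genes. Of 406 entries 394 were found in the table. Of the 161 pairs 47 passed, and 0 of the 47 held with a correlation estimated from the residuals of the fit (19 of them at an unadjusted p under 0.05). The fry test of limma was used as a check of direction. No list was chosen on these samples.

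The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison, the 12 largest rises and falls (8 at 24 against 8 days) among genes that passed, had replicate values of the 2 groups that did not overlap and reached a mean of 5 RPM, leaving out predicted genes and pseudogenes. With 3 libraries against 3, chance gives 10% of genes without overlap. It also took all measured members of the writers, demethylation, MEK-ERK and Wnt lists (drawn in the heat map, with those of larger change named in the text) and up to 4 members with the largest change of each other list, from which examples were taken. A few genes that the rule took are not reported here. Genes of multicopy families and overlapping or antisense genes are uncertain, since the handling of shared reads is not stated.

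Replicate numbers were examined as a possible pairing through correlations of each library's deviations from its group means. They were 0.67, 0.12 and 0.40 for replicates 1, 2 and 3 of MEKi/L and GSK3i/L at 8 days, so these 2 groups were taken as possibly paired by number. An alternative fit with the replicate number as a block covered all libraries, including those of groups without such a pairing. The labels do not say what the numbers share. In the other 6 comparisons the groups did not meet this limit, and GSK3i/L at 24 days was examined only with GSK3i/L at 8 days.

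The long-minus-short score of a library was the mean log2 level of 40 long transcripts minus that of 40 short ones. Both lists were put together by hand after the first component of the variation within groups (37.2% of it) had been seen. Deviations of the score from its group means correlated with that component at −0.95 over the 14 libraries, as a description without a test.

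The fit was tested on simulated data with 200 genes changed. For MEKi/L against S/L, 41.5% of 2-fold and 92.5% of 4-fold changes were recovered (14144 and 14160 genes tested). For GSK3i/L at 24 against 8 days it was 23% and 89%. At most 9.1% of calls were false (2-fold, GSK3i/L against S/L). Alternatives were quantile normalization, centring on medians, no filter or a mean of at least 5 RPM, pseudocounts of 0.1 and 5 RPM, limma without trend and robust variances, only the 2 groups compared, the replicate block, no minimum fold, an estimated correlation in camera, Spearman in place of Pearson correlation and leaving out each library in turn. Trimmed mean scaling, the score as a covariate and limma-voom on whole reads recovered from the plain libraries were added after the data had been seen. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.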

Results

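Poly(A) RNA was sequenced from E14 mouse embryonic stem cells, an XY line kept without feeder cells on gelatin. Cells were moved into 1 of 4 media, each with leukaemia inhibitory factor (LIF). S/L was serum-containing medium. The other 3 shared serum-free N2B27 medium and differed in their inhibitors: MEKi/L held 1 µM of a MEK inhibitor, GSK3i/L held 3 µM of the GSK3 inhibitor CHIR99021, and 2i/L held both. Each medium had 3 libraries at 8 days, and GSK3i/L had 2 further libraries at 24 days, giving 14 libraries in 5 groups. The labels call the samples biological replicates and do not say whether they came from separate cultures, so the p-values measure only the spread between these samples. In 8 libraries the scaling total was between 10550000 and 15760000 reads per library, read from the values themselves. In the other 6 (S/L and GSK3i/L at 8 days) depth could only be approximated, at 8080000 to 18410000 reads. Between 13458 and 14234 genes per library reached 0.5 RPM. Whole-genome bisulfite sequencing of 24 further samples was not analysed here, so the level of DNA methylation itself was not examined.

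The first principal component held 45.3% of the variance, with S/L between −111.2 and −88.4 and 2i/L between 93.9 and 95.3. The second held 19.8%, with S/L between 44.8 and 48.2, MEKi/L between 41.4 and 56.4, and GSK3i/L between −46.9 and −26.3 at 8 days and at −77.1 and −73.5 at 24 days. Within groups, correlations of log2 values ran from 0.984 to 0.987 in 2i/L and from 0.947 to 0.973 in GSK3i/L at 8 days. Each library's score was the mean log2 level of 40 long transcripts (such as Ahnak, Dst and Macf1) minus that of 40 short ones (mostly of the respiratory chain). It was −2.49 ± 0.25 in S/L, −0.65 ± 1.44 in MEKi/L, −1.10 ± 1.65 in GSK3i/L at 8 days, 0.87 ± 0.09 in 2i/L and −3.22 ± 0.40 in GSK3i/L at 24 days (mean ± SD). Replicate 1 stood apart from its group in MEKi/L (0.99, against −1.70 and −1.24) and in GSK3i/L at 8 days (0.69, against −1.43 and −2.55).

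**Figure D1:**
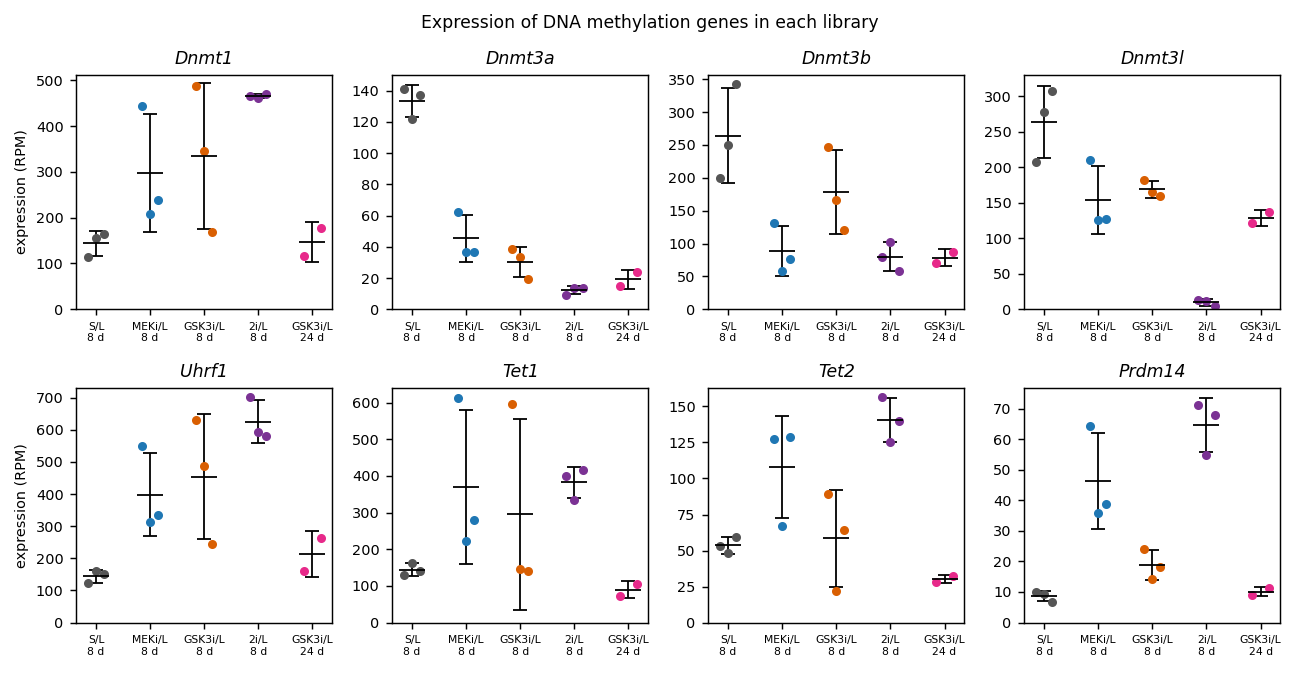
Expression in RPM (y axis) of 8 genes of DNA methylation and demethylation in each group (x axis). Points are single libraries, and horizontal bars with whiskers are the mean and SD (n = 3, and n = 2 for GSK3i/L at 24 days). Dnmt3l was at 9.63 ± 4.98 RPM in 2i/L and at 264 ± 50.9 RPM in S/L, and Dnmt3a was below its S/L level of 133 ± 10.3 RPM in every serum-free group.

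The comparison of MEKi/L with S/L asked how cells in serum-free medium with the MEK inhibitor differed from cells in serum, with basal medium and inhibitor changing together. The methylation writers did not pass as a list: 4 of 12 measured members rose, 2 fell and 6 did not pass. Their median was −0.06 (camera adjusted p = 0.62). The 2 that fell were the de novo DNA methyltransferase genes Dnmt3a and Dnmt3b. Dnmt3a (chromosome 12, 3806007 to 3914443, GRCm38) was at 45.3 ± 14.9 RPM against 133 ± 10.3 RPM, log2 fold change −1.60 ± 0.28 (mean ± SD, n = 3, and SE). Dnmt3b (chromosome 2, 153649450 to 153687730) was at 88.8 ± 37.5 RPM against 264 ± 72.4 RPM, log2 fold change −1.62 ± 0.33. Uhrf1, which brings the maintenance methyltransferase to replicating DNA, rose from 144 ± 19.8 to 398 ± 129.8 RPM (log2 fold change 1.43 ± 0.32). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling that ERK induces, fell from 81.5 ± 26.9 to 0.66 ± 0.51 RPM (log2 fold change −7.27 ± 0.66, limma adjusted p = 2.5e-06). In all, 2357 of 14980 tested genes rose at least 2-fold and 1453 fell.

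Members of the MEK-ERK list, made of genes that ERK signalling is known to induce, mostly fell in MEKi/L: 13 of 23 measured members fell, 4 rose and 6 did not pass, with 13 down and 4 up adjusted over the list alone. The immediate early genes Egr1 (log2 fold change −4.49 ± 0.73) and Myc (−3.27 ± 0.56), the ETS factor Etv4 (−3.12 ± 0.32) and the ERK phosphatase Dusp4 (−2.78 ± 0.39) were among them. The list median was −1.12 (adjusted p = 1.0e-04, and adjusted p = 0.59 with an estimated correlation). Formative and primed pluripotency genes also fell: 9 of 17 measured members fell, 2 rose and 6 did not pass, with 9 down and 2 up adjusted over the list alone, with a median of −1.56 (adjusted p = 9.6e-04, and adjusted p = 0.59 with an estimated correlation). Among them were Car4 (−4.82 ± 0.63), Pou3f1 (−3.83 ± 0.55) and Tcf15 (−3.34 ± 0.27). Naive pluripotency genes rose. For these, 10 of 16 measured members rose, 1 fell and 5 did not pass, with 11 up and 2 down adjusted over the list alone, at a median of 1.02 (adjusted p = 0.027, and adjusted p = 0.53 with an estimated correlation). Prdm14 (2.38 ± 0.25), which represses de novo methyltransferase genes, Tbx3 (2.32 ± 0.28) and Tfcp2l1 (2.31 ± 0.35) led this list.

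Of 16 listed two-cell-like genes 8 were tested, and all fell (also over the list alone). Their median was −4.42, or −3.38 with 4 members at 0 reads at their bound (adjusted p = 3.2e-08, and 0.31 with an estimated correlation). Zscan4d was at 0.063 ± 0.11 against 24.2 ± 9.18 RPM. Members near 0 without serum passed the filter only through S/L, so their falls were largely fixed beforehand. Most of the 8 are multicopy genes whose reads can be split between copies, so single levels are uncertain. Of the Wnt/beta-catenin targets, 8 of 20 measured members fell, 3 rose and 9 did not pass, with 8 down and 3 up adjusted over the list alone, with a median of −0.68 (−0.24 with 1 member at its bound, adjusted p = 0.035, and adjusted p = 0.61 with an estimated correlation). Sp5 (−4.50 ± 0.54), Sp8 (−2.82 ± 0.48) and Lef1 (−2.28 ± 0.33) were lower, and the list's call was lost after quantile normalization (adjusted p = 0.055) and without a filter on low values (adjusted p = 0.31). Among imprinted genes, 12 of 28 measured members fell, 4 rose and 12 did not pass, with 13 down and 5 up adjusted over the list alone, with a median of −0.57 (adjusted p = 0.003, and adjusted p = 0.32 with an estimated correlation), and without the filter adjusted p = 0.30. Peg10 (−3.81 ± 0.39) fell and Plagl1 (3.42 ± 0.56) rose. Cholesterol biosynthesis genes rose: 13 of 23 measured members rose, 0 fell and 10 did not pass, with 17 up and 0 down adjusted over the list alone, at a median of 0.64 (adjusted p = 8.2e-04, and adjusted p = 0.56 with an estimated correlation). Fdft1 was at 1.45 ± 0.16.

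The 12 largest rises in MEKi/L were Vax2, Hesx1, Pkd2l1, Bhmt, Gpnmb, Dio3, Vax2os1, Acoxl, Tnik, Osm, Lmx1b and Bhmt2, from 5.58 (Bhmt2) to 6.80 (Vax2). Hesx1 and Vax2 encode homeodomain factors of the early forebrain and eye. Vax2os1 had 0 reads in S/L and was at least 18-fold higher, against a floor of 3 reads per library. It lies beside Vax2 on the opposite strand, and the deposited coordinates of the 2 genes do not overlap. Named genes among the 12 largest falls, besides Spry4 and Zscan4d, were Porcn (−6.54 ± 0.56), Gjb1, Zscan4c, Gbp2, Tagln (−6.22 ± 0.44), Fndc3c1 and Plac8 (−6.20 ± 0.59), and the other 3 were gene models without an official symbol. Id1, a BMP target, fell (−6.18 ± 0.49), while Smad9 (4.92 ± 0.27) rose. The median of all genes was 0.17, which was not subtracted from the list medians. The long transcripts had a median log2 fold change of 1.04 and the short ones −0.85. Columns of the MEKi/L group were plain log2 RPM and those of S/L had been matched to a shared distribution. After quantile normalization 1933 genes were higher and 1809 lower, a share of 51.7% higher in place of 61.9%, and centring or trimmed mean scaling gave 1856 and 1888 or 1841 and 1889.

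**Figure D2:**
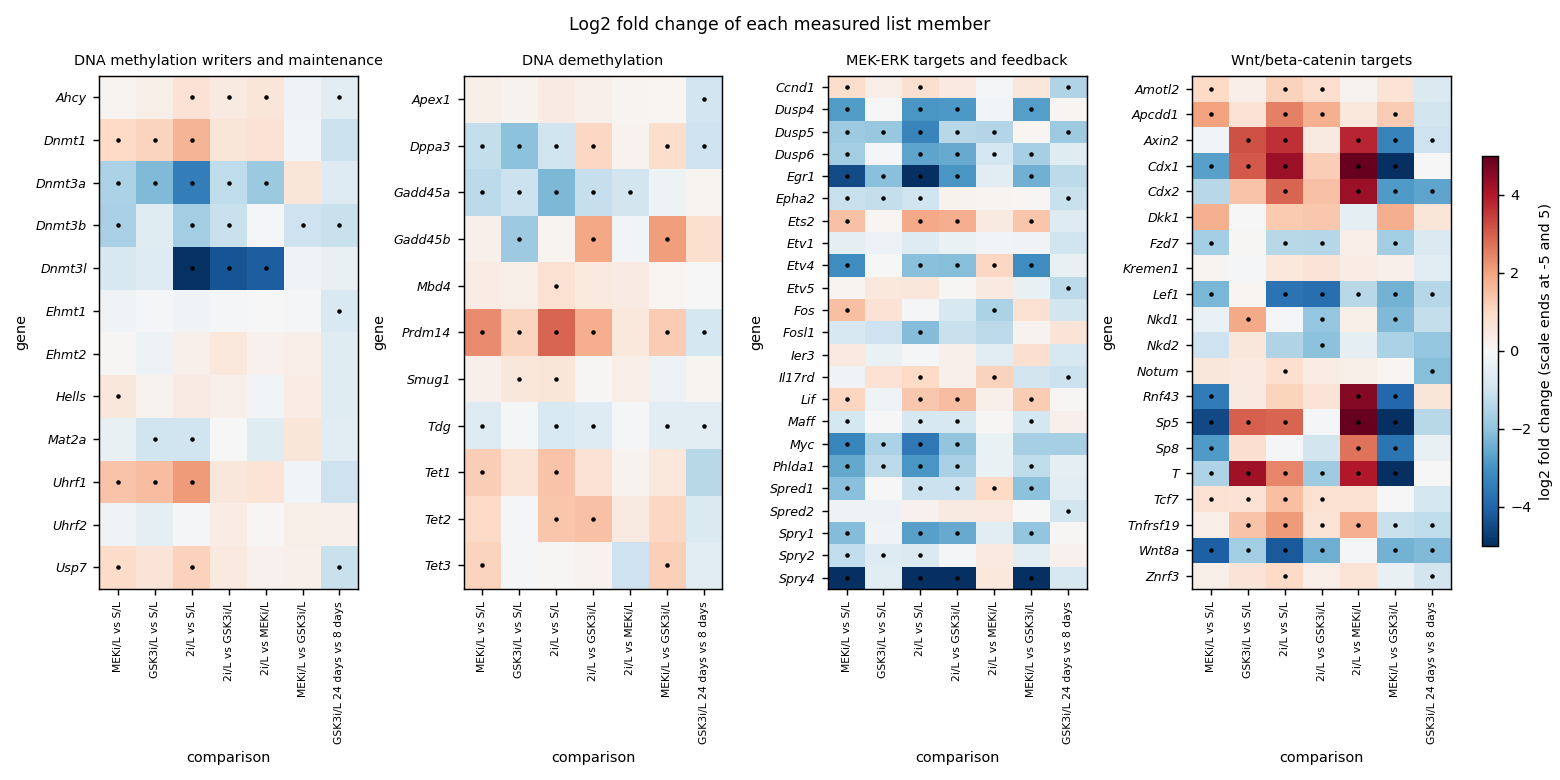
Log2 fold change (colour, from −5 to 5) of each measured member (rows) of 4 gene lists in the 7 comparisons (columns). Dots mark adjusted p under 0.05 (limma); Spry4 was lower in the 4 comparisons with the MEK inhibitor on the first side only, from −7.27 to −6.20, and Axin2 was lower in MEKi/L than in GSK3i/L at −3.34.

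GSK3i/L was compared with S/L in the same design, and both groups had been matched to 1 distribution. Axin2, a feedback gene of Wnt signalling (chromosome 11, 108920349 to 108950783), rose to 49.1 ± 11.3 RPM against 5.32 ± 0.99 RPM, log2 fold change 3.20 ± 0.24. Col3a1, encoding a fibrillar collagen of connective tissue (chromosome 1, 45311538 to 45349706), rose from 0.13 ± 0.12 to 86.7 ± 36.6 RPM (log2 fold change 9.12 ± 0.56). Dnmt3a fell to 30.2 ± 9.84 RPM against 133 ± 10.3 RPM, log2 fold change −2.19 ± 0.28, and Uhrf1 rose (1.56 ± 0.32). Dnmt3b (adjusted p = 0.17) and Dnmt3l (adjusted p = 0.18) did not pass, at 178 ± 63.9 and 169 ± 11.5 RPM. Pou3f1, a formative-stage POU factor, fell from 38.1 ± 10.6 to 1.00 ± 0.78 RPM (−5.56 ± 0.55). In all, 1407 genes rose and 1509 fell, and without S/L replicate 1 the lower count was 979.

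Of the Wnt/beta-catenin targets, 7 of 20 measured members rose, 1 fell and 12 did not pass, with 9 up and 1 down adjusted over the list alone, at a median of 0.69 (adjusted p = 0.0061, and adjusted p = 0.54 with an estimated correlation). The median was 0.44 with the long-minus-short score as a covariate. Besides Axin2, Cdx1 (3.06 ± 0.60) and Sp5 (2.98 ± 0.54) rose. Fibroblast and mesenchymal markers rose in GSK3i/L: 11 of 14 measured members rose, 1 fell and 2 did not pass, with 12 up and 1 down adjusted over the list alone. Their median was 2.12, or 1.63 with 2 members at their bound (adjusted p = 6.0e-05, and adjusted p = 0.31 with an estimated correlation). Col1a1 (3.38 ± 0.39) and Col1a2 (3.27 ± 0.53) rose, while Tagln, named after its values were seen, fell from 279 ± 109.7 to 61.1 ± 29.5 RPM (−2.21 ± 0.44). Cholesterol biosynthesis genes rose: 18 of 23 measured members rose, 0 fell and 5 did not pass, with 20 up and 0 down adjusted over the list alone, at a median of 0.87 (adjusted p = 3.6e-07, and adjusted p = 0.32 with an estimated correlation), led by Stard4 (1.31 ± 0.14) and Hmgcs1 (1.14 ± 0.22).

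Formative and primed genes fell in GSK3i/L: 9 of 17 measured members fell, 1 rose and 7 did not pass, with 9 down and 1 up adjusted over the list alone, with a median of −1.47 (adjusted p = 3.2e-05, and adjusted p = 0.49 with an estimated correlation). Car4 (−6.32 ± 0.63) and Fgf15 (−4.69 ± 0.49) fell besides Pou3f1. Germline genes with methylated promoters fell as well: 12 of 22 measured members fell, 1 rose and 9 did not pass, with 12 down and 1 up adjusted over the list alone, at a median of −0.85 (adjusted p = 4.4e-04, and adjusted p = 0.49 with an estimated correlation). The meiotic and germ cell genes Mael (−2.83 ± 0.43), Hormad1 (−2.25 ± 0.37) and Slc25a31 (−2.07 ± 0.49) were among them. All 8 tested two-cell-like genes fell (also over the list alone), at a median of −3.71 (adjusted p = 1.0e-07, and 0.31 with an estimated correlation). Naive pluripotency genes did not pass as a list: 8 rose, 1 fell and 7 did not pass, with 9 up and 3 down adjusted over the list alone, at a median of 0.74 (adjusted p = 0.062). They passed upward without a filter on low values (adjusted p = 0.0093) and with the long-minus-short score (0.0084). Of them, Tfcp2l1 (2.63 ± 0.35) and Klf4 (1.55 ± 0.25) rose and Dppa3 fell (−2.06 ± 0.26). Here, without the MEK inhibitor, MEK-ERK targets did not pass (6 of 23 fell, 0 rose, median −0.2, adjusted p = 0.15). They passed downward with the score (0.0018).

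Of the 12 largest rises, Cdh11, Fbn2, Smad9 and Col6a1 lay between 5.65 (Col6a1) and 6.48 (Cdh11). Tnc, Pglyrp1, Zic1 and Nkx1-2 had 1 to 3 reads in S/L, and the last 3 reached 21.6 ± 6.64, 15.4 ± 1.50 and 11.5 ± 2.55 RPM. The Wnt antagonist genes Dkk2 and Frzb and the limb mesenchyme factor Prrx1 had 0 reads in S/L, and each was at least 20-fold higher. The largest falls were Myo1f (−7.98 ± 0.49), Aass (−7.00 ± 0.41), AU015836, Zscan4d, Car4, Wt1 (at least 26-fold lower), Zscan4c, Pou3f1, Gbp1 (−5.53 ± 0.61) and 3 gene models without an official symbol. Medians were 0.06 for all tested genes, 0.70 for long and −0.80 for short transcripts. The share of higher genes, 48.3%, was 43.5% with trimmed mean scaling and 49.7% after quantile normalization.

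2i/L was compared with S/L to show the joint effect of both inhibitors and the serum-free medium. Dnmt3l, the catalytically inactive partner of the de novo methyltransferases, was at 9.63 ± 4.98 RPM against 264 ± 50.9 RPM, log2 fold change −4.93 ± 0.35 (n = 3, adjusted p = 1.4e-07). It lies at chromosome 10, 78041947 to 78063622 and overlaps Aire, and counting by strand is not stated, so reads of the pair are not told apart with certainty. Dnmt3a was at 12.2 ± 2.58 RPM against 133 ± 10.3 RPM, log2 fold change −3.47 ± 0.28, and Dnmt3b fell too (−1.72 ± 0.33). Uhrf1 rose from 144 ± 19.8 to 625 ± 66.7 RPM (2.12 ± 0.32), Prdm14 rose from 8.71 ± 1.71 to 64.7 ± 8.77 RPM (2.90 ± 0.25), and the naive factor Tfcp2l1 rose from 79.5 ± 19.7 to 1191 ± 51.1 RPM (3.94 ± 0.35). Dnmt1 rose (1.71 ± 0.35), but its call ended with the long-minus-short score as a covariate (log2 fold change 0.22, adjusted p = 0.50). In all, 3543 genes rose and 2770 fell.

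Formative and primed genes fell in 2i/L: 13 of 17 measured members fell, 1 rose and 3 did not pass, with 13 down and 1 up adjusted over the list alone, at a median of −2.10 (adjusted p = 1.8e-06, and adjusted p = 0.37 with an estimated correlation). Pou3f1 (−6.26 ± 0.55), Sox3 (−5.11 ± 0.50) and Tcf15 (−4.78 ± 0.27) showed the change, and Car4 was at 0.044 ± 0.076 RPM against 16.2 ± 2.35 RPM. MEK-ERK targets fell: 14 of 23 measured members fell, 4 rose and 5 did not pass, with 14 down and 4 up adjusted over the list alone, at a median of −0.99 (adjusted p = 0.0014, and adjusted p = 0.65 with an estimated correlation), with adjusted p = 0.056 without a filter on low values and a median of −1.54 with the score. Spry4 (−6.74 ± 0.66), Myc (−3.59 ± 0.56) and Dusp5 (−3.29 ± 0.29) fell, and Ets2 (1.91 ± 0.24) rose. All 8 tested two-cell-like genes fell (also over the list alone). Their median was −4.46, or −3.83 with 6 members at their bound (adjusted p = 4.2e-06, and 0.32 with an estimated correlation). Among imprinted genes, 14 of 28 measured members fell, 5 rose and 9 did not pass, with 14 down and 5 up adjusted over the list alone, at a median of −0.98 (adjusted p = 0.0054, and adjusted p = 0.32 with an estimated correlation), with adjusted p = 0.16 without the filter. Cdkn1c, a maternally expressed growth inhibitor, fell (−4.53 ± 0.24), as did Dlk1 (−5.36 ± 0.76), while Plagl1 rose (6.59 ± 0.56). For cholesterol biosynthesis, 18 of 23 measured members rose, 1 fell and 4 did not pass, with 18 up and 1 down adjusted over the list alone, at a median of 0.80 (adjusted p = 0.0048, and adjusted p = 0.59 with an estimated correlation), and centring gave a median of 0.49 with 12 members up. Stard4 was at 1.43 ± 0.14.

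The other 18 lists did not pass in this comparison. For naive pluripotency, 11 rose, 4 fell and 1 did not pass, with 11 up and 4 down adjusted over the list alone, at a median of 1.54 (adjusted p = 0.073). Tfcp2l1, Prdm14, Tbx3 (2.66 ± 0.28) and Nr5a2 (2.52 ± 0.27) led its rises. This list passed upward after quantile normalization (adjusted p = 0.027), without a filter on low values (adjusted p = 4.3e-04) and with the score (adjusted p = 0.0011). For general pluripotency, 3 rose, 5 fell and 2 did not pass, with 3 up and 5 down adjusted over the list alone, at a median of −0.57 (adjusted p = 0.13). Dppa2 was at −3.22 ± 0.28. For methylation writers, 4 rose, 4 fell and 4 did not pass, with 4 up and 4 down adjusted over the list alone, at a median of 0.08 (adjusted p = 0.6), where the mean was −0.42 and the median was −0.14 after quantile normalization. With the score the writers passed downward here (median −0.29, adjusted p = 0.019), in 2i/L against GSK3i/L (0.0074) and against MEKi/L (0.012), but not without it (0.60 in each). For demethylation genes, 5 rose, 3 fell and 3 did not pass, with 5 up and 3 down adjusted over the list alone, at a median of 0.41 (adjusted p = 0.92). Gadd45a was at −2.23 ± 0.21. For Wnt/beta-catenin targets, 11 rose, 3 fell and 6 did not pass, with 11 up and 3 down adjusted over the list alone, at a median of 1.14 (adjusted p = 0.26). Axin2 was at 3.66 ± 0.24, Cdx1 at 4.29 ± 0.60 and Lef1 at −3.67 ± 0.33. For LIF-STAT3 targets, 10 rose, 2 fell and 1 did not pass, with 10 up and 3 down adjusted over the list alone, at a median of 1.39 (adjusted p = 0.088). Klf4 was at 2.42 ± 0.25. For BMP-SMAD and ID genes, 4 rose, 5 fell and 2 did not pass, with 4 up and 5 down adjusted over the list alone, at a median of 0.35 (adjusted p = 0.7). Smad9 was at 6.77 ± 0.27 and Id1 at −4.79 ± 0.49.

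Lineage markers moved both ways. For primitive endoderm markers, 3 rose, 7 fell and 5 did not pass, with 4 up and 7 down adjusted over the list alone, at a median of −0.65 (adjusted p = 0.26). Lama1 was at 3.25 ± 0.36 and Lrp2 at −2.98 ± 0.43. For primitive streak and mesoderm markers, 6 rose, 1 fell and 3 did not pass, with 6 up and 1 down adjusted over the list alone, at a median of 1.46 (adjusted p = 0.21). Gsc was at 6.59 ± 0.33. For neural markers, 2 rose, 6 fell and 2 did not pass, with 2 up and 6 down adjusted over the list alone, at a median of −0.76 (adjusted p = 0.13). Neurod1 was at −3.91 ± 0.36. For trophoblast markers, 7 rose, 2 fell and 3 did not pass, with 7 up and 2 down adjusted over the list alone, at a median of 1.35 (adjusted p = 0.29). Tfap2a was at 3.52 ± 0.24. For fibroblast and mesenchymal markers, 5 rose, 4 fell and 5 did not pass, with 5 up and 4 down adjusted over the list alone, at a median of 0.50 (adjusted p = 0.76), where the test pointed down while the median (0.30 with 2 members at their bound) and the mean (0.10) were positive. Tagln was at −5.92 ± 0.44. For germline genes, 4 rose, 10 fell and 8 did not pass, with 4 up and 10 down adjusted over the list alone, at a median of −0.87 (adjusted p = 0.054). Mael was at −3.78 ± 0.43.

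Among stress, metabolism and chromatin lists, for p53 targets 6 rose, 5 fell and 6 did not pass, with 6 up and 5 down adjusted over the list alone, at a median of 0.40 (adjusted p = 0.71). Cdkn1a was at 2.85 ± 0.31. For ATF4 and amino acid stress genes, 8 rose, 1 fell and 8 did not pass, with 8 up and 1 down adjusted over the list alone, at a median of 0.46 (adjusted p = 0.33). Asns was at 2.17 ± 0.21. For glycolysis and hypoxia, 5 rose, 7 fell and 6 did not pass, with 5 up and 7 down adjusted over the list alone, at a median of −0.03 (adjusted p = 0.28). Bnip3 was at −5.31 ± 0.50 and Hk1 at 3.65 ± 0.37. For Polycomb genes, 6 rose, 2 fell and 6 did not pass, with 6 up and 2 down adjusted over the list alone, at a median of 0.35 (adjusted p = 0.46). Bmi1 was at 2.41 ± 0.20. For mitochondrially encoded genes, 1 rose, 0 fell and 9 did not pass, with 0 up and 0 down adjusted over the list alone, at a median of 0.36 (adjusted p = 0.63). With the score, general pluripotency (adjusted p = 1.6e-05), primitive endoderm markers (0.0021), neural markers (0.0074) and glycolysis and hypoxia (0.0036) also passed downward. Without the filter, Wnt/beta-catenin targets (adjusted p = 0.017), LIF-STAT3 targets (0.0011), trophoblast markers (0.034), ATF4 and amino acid stress (0.015) and Polycomb genes (0.034) passed upward.

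The 12 largest rises in 2i/L included Bhmt2 (7.57 ± 0.39), Bhmt (6.95 ± 0.45) and Dmgdh (7.21 ± 0.21), which encode enzymes of betaine and dimethylglycine metabolism. Mal, Osm, Smad9, Gsc, Plagl1 and Vax2 were the others above 3 reads in S/L. Nkx1-2, S1pr1 and Ccbe1 had 1 to 3 reads in S/L and reached 35.3 ± 2.92, 10.7 ± 1.78 and 11.8 ± 1.85 RPM. The falls were led by Plac8 (0.14 ± 0.13 RPM against 129.5 ± 32.2 RPM, log2 fold change −9.80 ± 0.59). Spink3 had 0 reads in 2i/L and was at least 210-fold lower, Zscan4d at least 100-fold and Enpp2 at least 40-fold. Aass (−7.35 ± 0.41), Myo1f, AU015836, Sema3e, Car4, Slc39a8, Gbp2 and 1 gene model without an official symbol made up the rest. All tested genes had a median of 0.28. Long transcripts had a median of 1.83 and short ones −1.65, and with the long-minus-short score as a covariate 1760 genes were higher and 1348 lower. This comparison also set plain against matched columns: centring gave 2453 higher and 3552 lower genes (40.8% higher in place of 56.1%), and trimmed mean scaling 2397 and 3594.

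**Figure D3:**
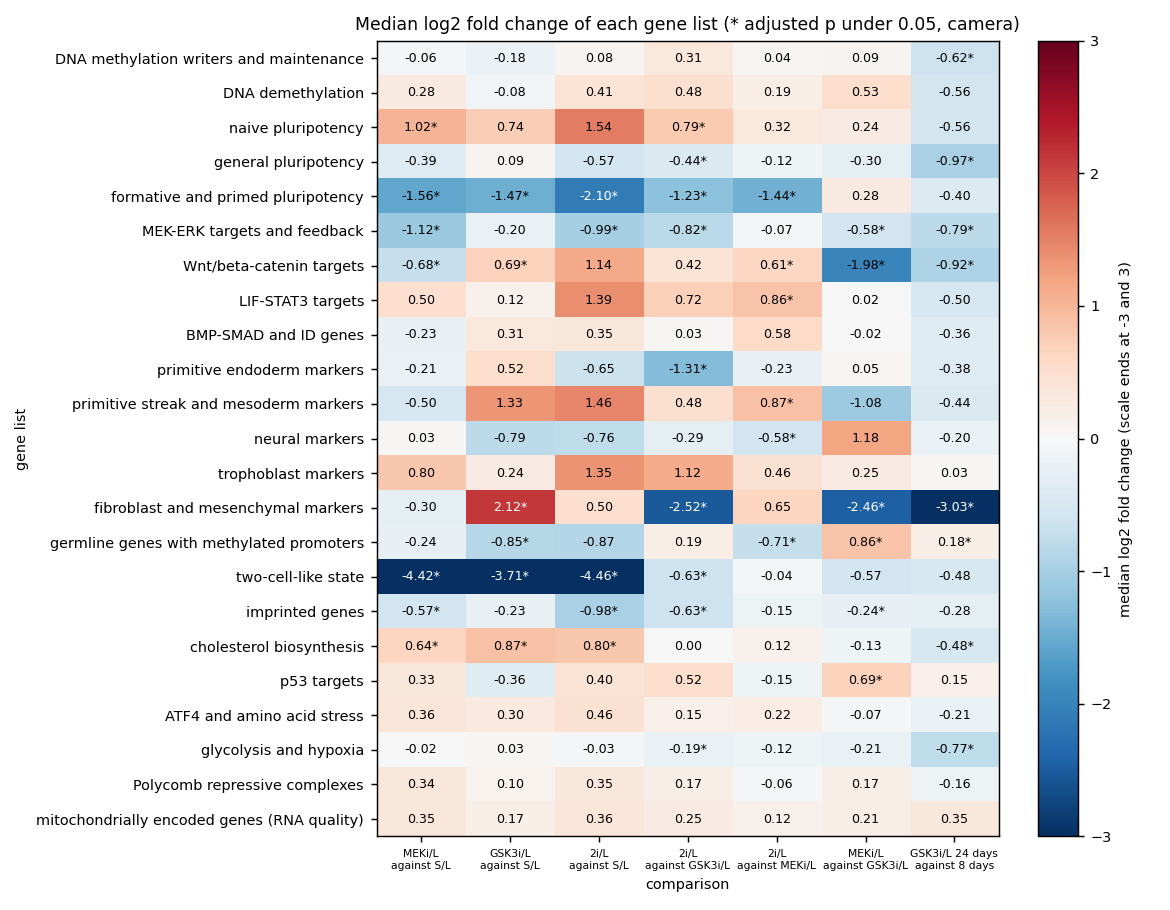
Median log2 fold change (number and colour, from −3 to 3) of each of the 23 gene lists (rows) in the 7 comparisons (columns). Asterisks mark lists with adjusted p under 0.05 in the camera test, such as the fibroblast and mesenchymal markers at 2.12 in GSK3i/L against S/L and at −3.03 in GSK3i/L at 24 against 8 days; 0 of the 47 kept this with an estimated correlation (19 at an unadjusted p under 0.05).

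Comparing 2i/L with GSK3i/L added the MEK inhibitor in 1 basal medium with GSK3 inhibited on both sides. Dnmt3l fell from 169 ± 11.5 to 9.63 ± 4.98 RPM (log2 fold change −4.30 ± 0.35, n = 3). Dnmt3a fell further (−1.28 ± 0.28), and Prdm14 rose from 18.8 ± 4.90 to 64.7 ± 8.77 RPM (1.80 ± 0.25). Spry4 was at 1.00 ± 0.98 RPM against 58.7 ± 29.3 RPM, log2 fold change −6.20 ± 0.66. The collagen gene Col3a1 fell from 86.7 ± 36.6 to 1.84 ± 0.17 RPM (−5.47 ± 0.56). In all, 1474 genes rose and 987 fell, and without GSK3i/L replicate 1 the lower count was 1498.

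MEK-ERK targets fell again: 11 of 23 measured members fell, 2 rose and 10 did not pass, with 11 down and 2 up adjusted over the list alone, at a median of −0.82 (adjusted p = 3.2e-04, and adjusted p = 0.62 with an estimated correlation), and without a filter on low values adjusted p = 0.11. Dusp6 (−2.53 ± 0.27), Spry1 (−2.52 ± 0.28), Dusp4 (−2.89 ± 0.39) and Etv4 (−2.11 ± 0.32) fell. Fibroblast and mesenchymal markers fell: 9 of 14 measured members fell, 0 rose and 5 did not pass, with 9 down and 1 up adjusted over the list alone, at a median of −2.52, or −2.14 with 1 member at its bound (adjusted p = 3.2e-08, and adjusted p = 0.15 with an estimated correlation). Acta2 was at −3.14 ± 0.37 and Tagln at −3.71 ± 0.44. Naive genes rose (9 of 16 measured members rose, 1 fell and 6 did not pass, with 11 up and 1 down adjusted over the list alone), at a median of 0.79 (adjusted p = 0.047, and adjusted p = 0.59 with an estimated correlation), or 0.48 after centring. Prdm14 and Tbx3 (1.16 ± 0.28) were examples. Formative and primed genes fell (8 of 17 measured members fell, 1 rose and 8 did not pass, with 8 down and 2 up adjusted over the list alone), at a median of −1.23, or −1.13 with 1 member at its bound (adjusted p = 9.5e-04, and adjusted p = 0.59 with an estimated correlation), and without the filter adjusted p = 0.10. Sox3 (−4.84 ± 0.50) and Lin28b (−1.98 ± 0.22) fell, whereas Otx2 rose (2.03 ± 0.29).

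General pluripotency genes were lower as a list: 4 of 10 measured members fell, 2 rose and 4 did not pass, with 4 down and 2 up adjusted over the list alone, at a median of −0.44 (adjusted p = 0.039, and adjusted p = 0.65 with an estimated correlation), which was lost after quantile normalization (adjusted p = 0.16) and without the filter (adjusted p = 0.39). Lin28a (−1.81 ± 0.30) and Utf1 (−1.68 ± 0.32) fell. For primitive endoderm markers, 7 of 15 measured members fell, 3 rose and 5 did not pass, with 8 down and 3 up adjusted over the list alone, at a median of −1.31 (adjusted p = 0.0097, and adjusted p = 0.67 with an estimated correlation), lost after quantile normalization (adjusted p = 0.12) and without the filter (adjusted p = 0.32). Col4a1 (−2.09 ± 0.36) was an example. For imprinted genes, 9 of 28 measured members fell, 4 rose and 15 did not pass, with 10 down and 4 up adjusted over the list alone, at a median of −0.63 (adjusted p = 8.2e-04, and adjusted p = 0.31 with an estimated correlation), and without the filter adjusted p = 0.11. The fetal growth factor gene Igf2 fell from 85.8 ± 11.2 to 9.31 ± 1.40 RPM (−3.21 ± 0.25), and Mest (−2.62 ± 0.23) also fell. Glycolysis and hypoxia genes were lower: 5 of 18 measured members fell, 1 rose and 12 did not pass, with 6 down and 1 up adjusted over the list alone, at a median of −0.19 (adjusted p = 0.031, and adjusted p = 0.65 with an estimated correlation), lost after quantile normalization (adjusted p = 0.18) and without the filter (adjusted p = 0.55). Pdk1 (−2.56 ± 0.23), Egln3 (−2.94 ± 0.28) and Bnip3 (−3.27 ± 0.50) fell. The two-cell-like list passed (adjusted p = 0.047, and adjusted p = 0.65 with an estimated correlation) although 0 of its 8 members did by limma (2 at an unadjusted p under 0.05), 0 also adjusted over the list alone. With 6 members at their bound its median was 0.00, and the call was lost after quantile normalization (adjusted p = 0.33), without the filter (adjusted p = 0.20) and with the score (adjusted p = 0.30). With the score as a covariate the medians were −0.86 for general pluripotency, −1.85 for formative and primed genes and −0.38 for glycolysis and hypoxia, and these lists still passed. Centring gave medians of −0.75 for general pluripotency, with 6 members down and 0 up, −0.49 for glycolysis and hypoxia and −0.94 for the two-cell-like list, against −0.63 before, and quantile normalization gave −0.12 for glycolysis and hypoxia.

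Among the largest rises were Bhmt (20.5 ± 3.30 RPM against 0.091 ± 0.091 RPM), Aspa (at least 27-fold higher), Mal, Kcnd3, Sh3rf2, Gsc, Ttll6, St8sia5, Calcoco2, Chst3 and Rims1, of which Mal (5.74 ± 0.57) and Kcnd3 (5.74 ± 0.44) were the largest above 3 reads in GSK3i/L. The largest falls were Dkk2 (at least 31-fold lower), Col6a2 (at least 27-fold), Col6a1, Frzb, Zic1 (−6.46 ± 0.74), Prrx1, Spry4, Plac8, Cdh11 (−5.82 ± 0.60), Colec12, Spn and Col3a1. The median of all genes was 0.18. Long transcripts had a median of 1.18 and short ones −0.82, and with their score as a covariate 940 genes were higher. Centring gave 844 higher and 1577 lower genes (34.9% higher in place of 59.9%) and trimmed mean scaling 942 and 1362, again across plain and matched columns.

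Comparing 2i/L with MEKi/L added the GSK3 inhibitor with MEK inhibited on both sides, and both groups were plain log2 RPM. Axin2 rose from 4.87 ± 1.35 to 67.0 ± 9.65 RPM (log2 fold change 3.81 ± 0.24, n = 3), and Sp5, a direct Wnt target and feedback repressor, rose from 0.16 ± 0.20 to 23.2 ± 6.71 RPM (7.41 ± 0.54). Dnmt3l fell from 154 ± 48.0 to 9.63 ± 4.98 RPM (−4.13 ± 0.35), and Dnmt3a fell (−1.87 ± 0.28). Tfcp2l1 rose (1.63 ± 0.35). In all, 479 genes rose and 793 fell. These counts were 868 and 1323 without MEKi/L replicate 1, the lower count was 466 without replicate 2, and the higher count was 297 without replicate 3.

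Wnt/beta-catenin targets rose: 8 of 20 measured members rose, 1 fell and 11 did not pass, with 10 up and 1 down adjusted over the list alone, at a median of 0.61 (adjusted p = 1.5e-05, and adjusted p = 0.31 with an estimated correlation). Cdx1 was at 9.06 ± 1.01 RPM against 0.021 ± 0.037 RPM, Rnf43 at 1.73 ± 0.39 RPM against 0.021 ± 0.037 RPM, and Tnfrsf19 rose (1.79 ± 0.23). LIF-STAT3 targets rose: 7 of 13 measured members rose, 0 fell and 6 did not pass, with 9 up and 0 down adjusted over the list alone, at a median of 0.86 (adjusted p = 1.4e-04, and adjusted p = 0.54 with an estimated correlation). Gbx2 was at 2.91 ± 0.26. Primitive streak and mesoderm markers, which share Cdx1, Cdx2 and T with the Wnt list, rose (4 of 10 measured members rose, 0 fell and 6 did not pass, with 4 up and 0 down adjusted over the list alone) at a median of 0.87 (adjusted p = 0.0075, and adjusted p = 0.34 with an estimated correlation), and without the filter adjusted p = 0.060. Formative and primed genes fell (10 of 17 measured members fell, 1 rose and 6 did not pass, with 11 down and 1 up adjusted over the list alone), at a median of −1.44 (adjusted p = 2.8e-07, and adjusted p = 0.32 with an estimated correlation), with Car4 at 0.044 ± 0.076 RPM against 0.60 ± 0.20 RPM (a call that ended with a pseudocount of 5 RPM, adjusted p = 0.73). Neural markers fell (3 of 10 measured members fell, 0 rose and 7 did not pass, with 6 down and 0 up adjusted over the list alone), at a median of −0.58 (adjusted p = 8.2e-04, and adjusted p = 0.32 with an estimated correlation), and 5 members fell after quantile normalization or centring. Neurod1 was at −3.08 ± 0.36 and Elavl3 at −1.96 ± 0.38. Germline genes fell (8 of 22 measured members fell, 0 rose and 14 did not pass, with 9 down and 0 up adjusted over the list alone), at a median of −0.71 (adjusted p = 1.4e-04, and adjusted p = 0.4 with an estimated correlation). Mael was at −2.25 ± 0.43.

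With the score as a covariate the medians were 0.39 for Wnt/beta-catenin targets, 0.55 for LIF-STAT3 targets and −1.01 for neural markers, and these lists still passed. The largest rises were Nkx1-2 (0 reads in MEKi/L, at least 150-fold higher), Sp5, Cdx1, Serpinb6b (5.91 ± 0.77), Ntn1 (5.57 ± 0.45), Lhfpl2, Pdzrn3, Rerg, Ccbe1, AA986860, S1pr1 and Calb2 (3.89). The largest falls were Crabp2 (−5.30 ± 0.38), Wnt5a (−5.17 ± 0.56), Ctnna2, Aire, Gstt1, Dnmt3l, Col5a3, Dpysl4, Col4a1, Crmp1, Calca and Ppp1r16b (−3.76). Over all tested genes the median was 0.07, with 0.73 for long and −0.86 for short transcripts. The share of higher genes, 37.7%, was 48.1% after quantile normalization (496 higher, 535 lower), 26.9% after centring (361 and 981) and 26.2% with trimmed mean scaling (351 and 989).

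MEKi/L and GSK3i/L were compared directly, since the series title names distinct effects of the inhibitors. Sp5 was at 0.16 ± 0.20 RPM against 23.8 ± 2.89 RPM, log2 fold change −7.48 ± 0.54 (MEKi/L first), and Axin2 was lower in MEKi/L (−3.34 ± 0.24). Spry4 was lower (−6.73 ± 0.66, n = 3), as was Col3a1 (−9.26 ± 0.56). Otx2, a factor of the formative state and forebrain, was at 130.1 ± 9.19 RPM in MEKi/L and 11.3 ± 4.01 RPM in GSK3i/L (3.59 ± 0.29), and Brdt, a testis bromodomain gene of the germline list, at 3.14 ± 0.23 and 0.43 ± 0.22 RPM (3.03 ± 0.47). In all, 1295 genes were higher in MEKi/L and 624 lower. Dnmt3b (−1.02 ± 0.33, adjusted p = 0.043) was the only methylation writer to pass. Its call ended with the replicate block (adjusted p = 0.052), and without GSK3i/L replicate 1 (0.13) or 2 (0.095) or MEKi/L replicate 2 (0.17) or 3 (0.13).

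In MEKi/L relative to GSK3i/L, Wnt/beta-catenin targets were lower (12 of 20 measured members fell, 1 rose and 7 did not pass, with 13 down and 3 up adjusted over the list alone), at a median of −1.98, or −1.66 with 1 member at its bound (adjusted p = 3.2e-08, and adjusted p = 0.21 with an estimated correlation). MEK-ERK targets were lower (9 of 23 measured members fell, 2 rose and 12 did not pass, with 12 down and 4 up adjusted over the list alone), at a median of −0.58 (adjusted p = 3.6e-04, and adjusted p = 0.62 with an estimated correlation), and without the filter adjusted p = 0.057. Etv4 (−3.12 ± 0.32), Dusp4 (−2.75 ± 0.39) and Spred1 (−2.07 ± 0.19) were among them. Fibroblast and mesenchymal markers were lower (8 of 14 measured members fell, 0 rose and 6 did not pass, with 11 down and 0 up adjusted over the list alone), at a median of −2.46, or −1.82 with 2 members at their bound (adjusted p = 4.4e-12, and adjusted p = 0.066 with an estimated correlation). Col1a1 was at −5.04 ± 0.39 and Acta2 at −4.58 ± 0.37. Imprinted genes were lower as a list (8 of 28 measured members fell, 2 rose and 18 did not pass, with 8 down and 2 up adjusted over the list alone), at a median of −0.24 (adjusted p = 0.0048, and adjusted p = 0.32 with an estimated correlation), and without the filter adjusted p = 0.40. The median was −0.48 after quantile normalization and −0.41 after centring. Igf2 was at 3.65 ± 0.45 RPM against 85.8 ± 11.2 RPM, log2 fold change −4.55 ± 0.25. Germline genes were higher (8 of 22 measured members rose, 0 fell and 14 did not pass, with 13 up and 0 down adjusted over the list alone), at a median of 0.86 (adjusted p = 8.5e-04, and adjusted p = 0.53 with an estimated correlation), with Brdt, Dpep3 (2.78 ± 0.68) and Tuba3a (3.12 ± 0.20) among them. Tuba3a has near-identical copies in the genome, so its level is uncertain. Targets of p53 were higher (9 of 17 measured members rose, 1 fell and 7 did not pass, with 9 up and 1 down adjusted over the list alone), at a median of 0.69 (adjusted p = 0.015, and adjusted p = 0.65 with an estimated correlation). Plk2 was at 1.59 ± 0.28 and Btg2 at 1.25 ± 0.24.

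The largest rises in MEKi/L over GSK3i/L were Bhmt, Lrtm2 (6.74 ± 0.63), Ttll6 (6.36 ± 0.41), Sh3rf2, Chst3, Ctnna2, Dio3, Calcoco2, Atp2b2, Slc5a1, Hhip and Msln (5.10). The largest falls were Col3a1, Sp5, Spry4, Ntn1 (−6.60 ± 0.45), Ptgs1 (0.074 ± 0.066 RPM against 9.07 ± 3.39 RPM), Col6a1 (−6.18 ± 0.73), and 6 genes with 0 reads in MEKi/L: Tnc (at least 60-fold lower), Nkx1-2 (49-fold), Nt5e (35-fold), Dkk2, Prrx1 (30-fold each) and Ccdc80 (24-fold). Over all tested genes the median was 0.09, with 0.41 for long and −0.03 for short transcripts. The share of higher genes, 67.5%, was 55.7% after quantile normalization (1052 higher, 836 lower) and 56.5% after centring (1046 and 806).

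The response to each inhibitor was compared between comparisons that had no library in common. Log2 fold changes of MEKi/L against S/L and of 2i/L against GSK3i/L correlated across the 14980 genes with Pearson r = 0.62 and Spearman 0.67. Both comparisons had 966 higher genes in common (232 expected from independent lists) and 510 lower genes (96 expected), while 33 and 23 genes went opposite ways (155 and 143 expected). For the GSK3 inhibitor (GSK3i/L against S/L, and 2i/L against MEKi/L), r was 0.51 and Spearman 0.57, with 261 shared higher genes (45 expected), 339 shared lower genes (80 expected), and 21 and 14 genes going opposite ways (74 and 48 expected). Spry4, Dusp4 and Etv4 were lower in both MEK inhibitor comparisons, and Axin2 and Sp5 were higher in both GSK3 inhibitor comparisons. Genes are not independent replicates, so these values carry no p. Both MEK inhibitor comparisons set plain against matched columns, and long transcripts were higher in all 4 comparisons (medians 1.04, 1.18, 0.70 and 0.73).

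Longer culture in GSK3i/L was examined at 24 days against 8 days, with 2 libraries against 3 and no other medium at 24 days analysed here. The collagen gene Col3a1 fell from 86.7 ± 36.6 RPM at 8 days (n = 3) to 0 reads at 24 days (n = 2), at least 340-fold lower. Col1a1 fell from 56.7 ± 27.9 to 0.21 ± 0.079 RPM (log2 fold change −8.02 ± 0.43). Igf2 fell from 85.8 ± 11.2 to 6.04 ± 1.55 RPM (−3.85 ± 0.28), and Zic1 from 15.4 ± 1.50 to 0.21 ± 0.079 RPM (−6.26 ± 0.83). S100g, which encodes the calcium-binding protein calbindin D9k, rose from 0.29 ± 0.51 to 18.4 ± 10.9 RPM (6.51 ± 0.86). In all, 430 genes rose and 1064 fell. These counts depended on single libraries: 75 and 387 without 8-day replicate 1, 270 higher without 8-day replicate 2, 1403 and 1955 without 8-day replicate 3, 77 and 338 without 24-day replicate 2, and 24 and 343 without 24-day replicate 3.

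Fibroblast and mesenchymal markers fell with time: 12 of 14 measured members fell, 0 rose and 2 did not pass, with 13 down and 0 up adjusted over the list alone, at a median of −3.03, or −2.57 with 4 members at their bound (adjusted p = 1.5e-11, and adjusted p = 0.066 with an estimated correlation). Their median level per library was 4.39, 4.16 and 3.14 log2 RPM at 8 days and −0.93 and −1.42 at 24 days. Wnt/beta-catenin targets fell: 7 of 20 measured members fell, 0 rose and 13 did not pass, with 12 down and 0 up adjusted over the list alone, at a median of −0.92 (adjusted p = 0.0048, and adjusted p = 0.53 with an estimated correlation), with the Wnt-inactivating enzyme gene Notum at −2.14 ± 0.33. Cholesterol biosynthesis genes fell (8 of 23 measured members fell, 0 rose and 15 did not pass, with 14 down and 0 up adjusted over the list alone), at a median of −0.48 (adjusted p = 9.5e-04, and adjusted p = 0.56 with an estimated correlation), as did glycolysis genes (8 of 18 measured members fell, 2 rose and 8 did not pass, with 13 down and 2 up adjusted over the list alone), at a median of −0.77 (adjusted p = 0.028, and adjusted p = 0.65 with an estimated correlation). General pluripotency genes fell (4 of 10 measured members fell, 0 rose and 6 did not pass, with 7 down and 0 up adjusted over the list alone), at a median of −0.97 (adjusted p = 0.021, and adjusted p = 0.65 with an estimated correlation). Methylation writers fell (4 of 12 measured members fell, 0 rose and 8 did not pass, with 8 down and 0 up adjusted over the list alone), at a median of −0.62 (adjusted p = 0.022, and adjusted p = 0.65 with an estimated correlation), and with the long-minus-short score adjusted p = 0.10. MEK-ERK targets fell (6 of 23 measured members fell, 0 rose and 17 did not pass, with 6 down and 0 up adjusted over the list alone), at a median of −0.79 (adjusted p = 0.035, and adjusted p = 0.72 with an estimated correlation), a call lost without the filter (adjusted p = 0.066) and with the score (adjusted p = 0.59). Germline genes were higher as a list (2 of 22 measured members rose, 0 fell and 20 did not pass, with 1 up and 0 down adjusted over the list alone), at a median of 0.18 (adjusted p = 0.047, and adjusted p = 0.65 with an estimated correlation), lost after quantile normalization (adjusted p = 0.062) and with the score (adjusted p = 0.23). With the score the medians were smaller: −0.40 for general pluripotency, −0.53 for Wnt/beta-catenin targets and −0.46 for glycolysis, which still passed, and −0.24 for methylation writers, −0.21 for MEK-ERK targets and −0.01 for germline genes, which did not. After quantile normalization fewer members fell: 1 methylation writer, 2 general pluripotency genes, 4 Wnt/beta-catenin targets, 4 glycolysis genes and 5 cholesterol genes. Trimmed mean scaling gave 2 writers down and medians of −0.30 for cholesterol genes and 0.36 for germline genes, of which 4 rose. For mitochondrially encoded genes, a list taken as a sign of RNA quality, 1 rose, 0 fell and 9 did not pass, with 1 up and 0 down adjusted over the list alone, at a median of 0.35 (adjusted p = 0.054), and they passed upward with the replicate block (adjusted p = 0.049), without the filter (0.013) and with the score (median 0.46, adjusted p = 0.012), but not after quantile normalization (0.22) or with an estimated correlation (0.73).

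The 8 largest rises were S100g, Car4 (5.15 ± 0.70), Pitx1 (4.96 ± 0.68), Ctsh, Cited1, Cfd, Spink3 and Dpp4. The calls of the last 5 ended without 24-day replicate 2 (adjusted p = 0.24 for Ctsh, 0.16 for Cited1, 0.13 for Cfd, 0.23 for Spink3 and 0.30 for Dpp4). They also ended with the long-minus-short score as a covariate (adjusted p = 0.13, 0.058, 0.42, 0.19 and 0.10 in the same order). Without 8-day replicate 1, adjusted p was 0.076 for Ctsh, 0.14 for Cfd and 0.078 for Spink3. Without 8-day replicate 2 it was 0.077 for Cfd, 0.056 for Spink3 and 0.081 for Dpp4, and without 24-day replicate 3 it was 0.18 for Cfd. The 8 largest falls were Col3a1, Col1a1, Thbs1 (0.044 ± 0.062 RPM against 40.4 ± 10.4 RPM), Acta2 (0.076 ± 0.11 RPM against 35.8 ± 2.43 RPM), and Tnc, Col6a1, Col1a2 and Dkk2, which had 0 reads at 24 days and were at least 56-fold, 39-fold, 41-fold and 27-fold lower. Mest (−1.77 ± 0.26) and Ndn (−1.96 ± 0.28), both imprinted, also fell. The median of all genes was −0.19, and medians of long and short transcripts were −0.92 and 1.18. With the long-minus-short score as a covariate 54 genes were higher and 286 lower. The 24-day columns were plain and the 8-day columns matched, and after quantile normalization 466 genes were higher and 622 lower (42.8% higher in place of 28.8%), with 598 and 669 under trimmed mean scaling.

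**Figure D4:**
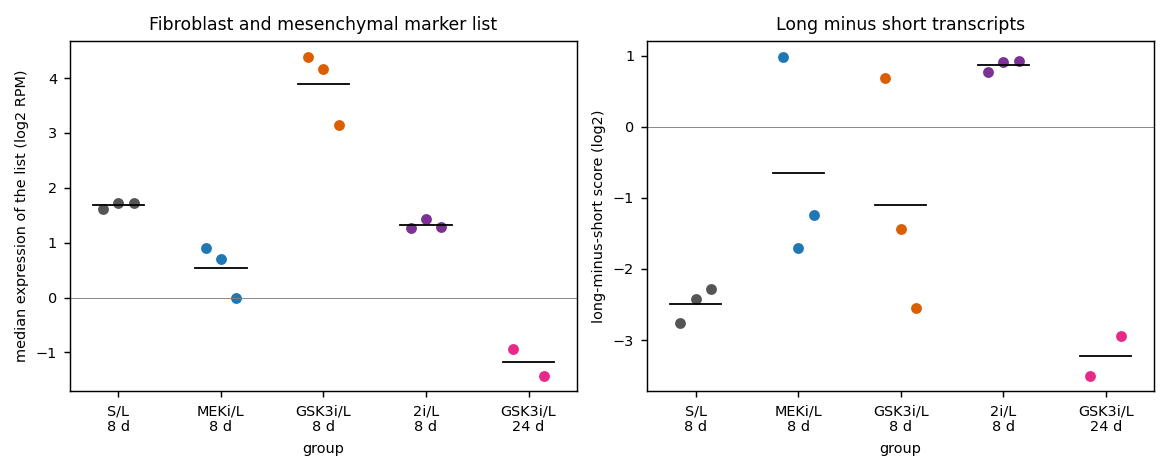
Left, median log2 RPM (y axis) of the fibroblast and mesenchymal marker list, and right, long-minus-short transcript score (log2, y axis), for each library (points) by group (x axis), with lines at the group means. The 3 libraries of GSK3i/L at 8 days lay between 3.14 and 4.39 on the left, above every other library, and on the right replicate 1 of MEKi/L (0.99) and of GSK3i/L at 8 days (0.69) lay near the 2i/L libraries.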

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

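The median rise of abundant fibroblast transcripts, the count of libraries above all others and the share of lower genes at 24 days after quantile normalization were tests chosen only after the result was seen, as were both tests with the long-minus-short score, and the fibroblast median after quantile normalization was chosen before it.

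In GSK3i/L, 8 of the 23 gene lists differed between 24 and 8 days by the camera test of that difference. Their median log2 fold changes at 24 against 8 days were −0.62 for DNA methylation writers (adjusted p = 0.022), −0.97 for general pluripotency (0.021), −0.79 for MEK-ERK targets (0.035), −0.92 for Wnt/beta-catenin targets (0.0048), −3.03 for fibroblast and mesenchymal markers (1.5e-11), 0.18 for germline genes (0.047), −0.48 for cholesterol biosynthesis (0.00095) and −0.77 for glycolysis and hypoxia (0.028). The median of all genes was −0.19. None of the 8 passed with an estimated correlation.

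Fibroblast and mesenchymal markers were high in GSK3i/L at 8 days and low at 24 days. All 3 libraries of 8 days had a list median above every other library, which argues against a single library as the source, and after quantile normalization the median at 24 against 8 days was −2.82, which argues against the matching of columns. Fibroblasts among the cells would bring all their abundant transcripts, but over 16 such transcripts the median rise over S/L was 0.2% of the rise of Col1a1 (51.7 RPM): Dcn stood at 0.047 RPM, S100a4 at 0.326 RPM and Col6a3 at 2.63 RPM, although Fstl1 and Timp1 reached 107.4% and 41% of it. Serum was also removed in this comparison, and Tagln (279 RPM), Lgals1 (141 RPM) and S100a6 (60.2 RPM) were high in S/L. The median over all 16 can therefore not decide the question. Among the 11 of them under 10 RPM in S/L the median rise was 0.2% and the highest 18.1% (Col1a2). This argues against fibroblasts for these 11 only. From 8 to 24 days in the same medium, Tagln fell from 61.1 to 2.39 RPM and Fstl1 from 123 to 66.6 RPM, while Lgals1 stayed at 102 RPM. The tested list holds 6 of the 16, and the labels describe a culture without feeders. Fibroblasts stay open, as do another cell type and time in culture, both untested.

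At 24 against 8 days of GSK3i/L, 1064 genes were lower and 430 higher, and the long-minus-short score also fell. With the score as a covariate 286 genes were lower and 54 higher: the median of the lower genes went from −1.47 (median SE 0.36) to −1.04 (0.37), with 262 of 1064 still called, and that of the higher genes from 1.46 (0.41) to 0.72 (0.29), with 37 of 430 still called, so calls ended mainly because folds became smaller. The transcripts of the score were picked after the variation within groups of these same libraries had been seen. Its short transcripts were mostly of the respiratory chain. The drop in calls therefore cannot tell transcript length or RNA integrity from a change in those genes. Lower genes made up 84.1% of the calls made with the score, where a larger part of the higher calls had ended. This argues against the trend that the score removes as the whole cause of the imbalance. Mitochondrially encoded genes, listed beforehand as a sign of RNA quality, had a median of 0.35 (adjusted p = 0.054), or 0.46 with the score (adjusted p = 0.012), so a difference in RNA quality outside the score stays open. After quantile normalization the lower share was 57.2%, between the limits set for and against an effect of the matching, and the columns of 24 and 8 days differ in that treatment altogether, so the 2 cannot be told apart, and time in culture, which the design names, stays open with only 2 libraries at 24 days.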

How the results depend on the processing

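The score covariate, trimmed mean scaling and limma-voom were chosen only after the result was seen. Many named genes were chosen for large folds and replicates without overlap in these same data, so a kept direction was largely fixed beforehand. Directions of all 293 pairs of a named gene and a comparison were the same under every alternative in which they were tested, and 284 pairs also kept their side of the threshold. In the other 9, the call of 8 was lost under at least 1 alternative (5 of them at 24 against 8 days), and Dnmt3b in GSK3i/L against S/L passed with the score (−1.11, adjusted p = 4.9e-04). No list that passed changed its direction. Of the 47 passing lists 0 passed with an estimated correlation in camera (19 at an unadjusted p under 0.05), while 49 pairs passed with the replicate block, 44 after quantile normalization, 53 without a filter and 64 with the score. Of these, 4, 3, 21 and 21 had not passed before, and 2, 6, 15 and 4 of the 47 were lost.

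The following counts moved by more than 1.5 times, given as higher and lower in the order of the comparisons. With a mean of at least 5 RPM, where fewer genes were tested, they were 1341 and 787 (MEKi/L against S/L), 718 and 776 (GSK3i/L against S/L), 1527 lower (2i/L against S/L), 973 and 331 (2i/L against GSK3i/L), 297 and 243 (2i/L against MEKi/L), 604 and 235 (MEKi/L against GSK3i/L) and 576 lower (24 against 8 days). A pseudocount of 5 RPM, which shrinks folds of low genes by construction, gave 882 and 660, 358 and 604, 1900 and 1356, 642 and 198, 213 and 136, 414 and 170, and 234 and 270 in the same order. Without a minimum fold, a looser limit, there were 3917 and 2201 genes in MEKi/L against S/L, 2516 higher in GSK3i/L against S/L, 5863 higher in 2i/L against S/L, 2969 higher in 2i/L against GSK3i/L, 1020 higher in 2i/L against MEKi/L and 1972 lower at 24 against 8 days.

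Centring on medians gave 844 higher and 1577 lower genes in 2i/L against GSK3i/L. Trimmed mean scaling gave 942 higher genes there and 669 lower at 24 against 8 days, and quantile normalization 622 lower at 24 against 8 days. With the score there were 1760 higher and 1348 lower genes in 2i/L against S/L, 940 higher in 2i/L against GSK3i/L, and 54 and 286 at 24 against 8 days. For the last comparison, limma without trend and robust variances gave 271 higher genes and a fit of only the 2 groups, with 3 residual degrees of freedom, 7 and 142. The cause was not tested for these. Correlations of fold changes with a mean of at least 5 RPM were 0.76 for the MEK inhibitor and 0.66 for the GSK3 inhibitor, and the Spearman value of the latter was 0.57. With the score they were 0.58 and 0.45.

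With the replicate number as a block the counts at 24 against 8 days were 171 and 630, and the lists that lost their call were the two-cell-like state in 2i/L against GSK3i/L (adjusted p = 0.054) and MEK-ERK targets at 24 against 8 days (adjusted p = 0.053). Correlations of same-numbered libraries at 24 and 8 days were −0.20 and −0.31, and 8 of the 14 libraries correlated best with their own number, which is a hint from the data only. No other count moved by more than 1.5 times with the block, and among named genes the calls of Dnmt3b in MEKi/L against GSK3i/L and of Cfd at 24 against 8 days were lost. For 4 lists with an adjusted p of 0.054 to 0.059 the block gave 0.044 to 0.049, none of them in MEKi/L against GSK3i/L, and it changed no other call.

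Leaving out 1 library at a time gave 1857 to 2468 higher and 1090 to 1655 lower genes in MEKi/L against S/L. Ranges were 1093 to 1892 and 979 to 2097 in GSK3i/L against S/L, and 3243 to 3620 and 2532 to 2756 in 2i/L against S/L. They were 1104 to 1934 and 738 to 1498 in 2i/L against GSK3i/L, and 297 to 868 and 466 to 1323 in 2i/L against MEKi/L. In MEKi/L against GSK3i/L they were 1096 to 1406 and 477 to 659. At 24 against 8 days the ranges were 24 to 1403 and 338 to 1955: 75 and 387 without 8-day replicate 1, 270 higher without 8-day replicate 2, 1403 and 1955 without 8-day replicate 3, 77 and 338 without 24-day replicate 2, and 24 and 343 without 24-day replicate 3, where the lone library is assumed to vary like the other groups. Correlations ranged from 0.57 to 0.63 and from 0.47 to 0.53. Limma-voom on recovered reads, possible for 2i/L against MEKi/L, called 483 higher and 937 lower of 14242 genes, and 1099 of the 1272 calls (86.4%) were shared. Depth limits genes near 0.25 RPM, at about 3 reads.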

Other observations

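Of the 3 tests of the X chromosome, those on genes of at least 20 RPM and with the long-minus-short score were chosen only after the result was seen.

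Genes outside the passing lists also moved in both single-inhibitor media against S/L. The general pluripotency factor genes Dppa2 (−2.34 ± 0.28 in MEKi/L and −1.74 ± 0.28 in GSK3i/L, log2 fold change ± SE, n = 3) and Dppa4 (−1.55 ± 0.18 and −1.14 ± 0.18) fell, and so did the mitophagy gene Bnip3 (−2.44 ± 0.50 and −2.04 ± 0.50) and Id1 in GSK3i/L (−2.75 ± 0.49). Hexokinase 1, Hk1, rose (2.85 ± 0.37 and 1.89 ± 0.37), as did asparagine synthetase, Asns (1.14 ± 0.21 and 2.02 ± 0.21), and the Polycomb gene Bmi1 (2.58 ± 0.20 and 1.17 ± 0.20). The cell cycle inhibitor gene Cdkn1a rose in GSK3i/L (2.19 ± 0.31), as the only riser among p53 targets, of which 1 rose, 6 fell and 10 did not pass, with 1 up and 6 down adjusted over the list alone, at a median of −0.36 (adjusted p = 0.059). That list passed downward without a filter (adjusted p = 0.022) and with the score (0.020). None of the lists of these genes passed in either comparison. For general pluripotency, 3 rose, 3 fell and 4 did not pass, with 3 up and 3 down adjusted over the list alone, at a median of −0.39 (adjusted p = 0.23) in MEKi/L, and 0 rose, 2 fell and 8 did not pass, with 0 up and 2 down adjusted over the list alone, at a median of 0.09 (adjusted p = 0.58) in GSK3i/L. For glycolysis and hypoxia, which holds Bnip3 and Hk1, 6 rose, 6 fell and 6 did not pass, with 6 up and 6 down adjusted over the list alone, at a median of −0.02 (adjusted p = 0.52) in MEKi/L, and 4 rose, 3 fell and 11 did not pass, with 4 up and 3 down adjusted over the list alone, at a median of 0.03 (adjusted p = 0.75) in GSK3i/L. For Polycomb genes, 6 rose, 1 fell and 7 did not pass, with 6 up and 1 down adjusted over the list alone, at a median of 0.34 (adjusted p = 0.12) in MEKi/L, and 3 rose, 0 fell and 11 did not pass, with 3 up and 0 down adjusted over the list alone, at a median of 0.10 (adjusted p = 0.63) in GSK3i/L. General pluripotency passed downward with the score (adjusted p = 0.0047 in MEKi/L and 0.029 in GSK3i/L), and without a filter ATF4 and amino acid stress (adjusted p = 0.022 and 0.047) and, in MEKi/L, Polycomb genes (0.0020) passed upward. For BMP-SMAD and ID genes, 3 rose, 4 fell and 4 did not pass, with 4 up and 4 down adjusted over the list alone, at a median of −0.23 (adjusted p = 0.6) in MEKi/L, and 2 rose, 2 fell and 7 did not pass, with 2 up and 2 down adjusted over the list alone, at a median of 0.31 (adjusted p = 0.78) in GSK3i/L. For ATF4 and amino acid stress, 5 rose, 1 fell and 11 did not pass, with 5 up and 1 down adjusted over the list alone, at a median of 0.36 (adjusted p = 0.36) in MEKi/L, and 6 rose, 1 fell and 10 did not pass, with 6 up and 1 down adjusted over the list alone, at a median of 0.30 (adjusted p = 0.14) in GSK3i/L.

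X-linked genes were lower relative to autosomal genes in 2i/L than in S/L. The difference of medians was −0.37 ± 0.05 (SE, n = 3 and 3 libraries, 512 X-linked and 14452 autosomal genes), with −0.20, −0.24 and −0.19 in the 2i/L libraries and 0.25, 0.10 and 0.13 in S/L. It was −0.23 ± 0.05 in MEKi/L and −0.07 ± 0.07 in GSK3i/L against S/L. Without multicopy families and unnamed gene models it was −0.31 ± 0.03, which argues against reads shared between copies. Genes near the detection limit (−0.21 ± 0.05 at 20 RPM or more) and transcript length or RNA integrity (−0.20 ± 0.08 with the score) could each account for part of it and cannot be told apart from it here, since both values lie within 1 SE of the limit of −0.20 set for the tests, and no biological explanation was tested.

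Each comparison of 3 against 3 libraries has 10 splits into 3 and 3, too few for a share under 0.05. Every split other than the real one has libraries of both media on each side. The difference between media then enters the spread within sides, so low counts there were largely fixed beforehand. The real split, 1 of 10, called 3810 genes in MEKi/L against S/L, 2916 in GSK3i/L against S/L, 6313 in 2i/L against S/L, 2461 in 2i/L against GSK3i/L and 1272 in 2i/L against MEKi/L, and the highest of the other splits called 0 in each with limma. At an unadjusted p under 0.05 those other splits reached at most 261, 960, 192, 541 and 450 genes, against 4137, 3348, 6444, 2982 and 2010 for the real split. In MEKi/L against GSK3i/L the real split called 1919 genes and the highest other 810, which set replicates 1 and 2 of GSK3i/L and replicate 1 of MEKi/L against the rest and parts 1 of the 3 pairs. The other 3 splits that part all 3 pairs called 0 genes each with limma (112, 112 and 73 at an unadjusted p under 0.05), where the real split had 2386.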
